A study of Tachysurus vachellii and Tachysurus fulvidraco x Tachysurus vachelli and Tachysurus fulvidraco with 9 samples.

How the data were processed

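Juvenile livers of P. vachelli, P. fulvidraco and the hybrid Huangyou-1 were profiled by small RNA sequencing, in 9 libraries of 3 groups. Per the labels, libraries were made with the TruSeq Small RNA kit, sequenced on an Illumina HiSeq instrument, and filtered and annotated by the authors with ACGT101-miR. The table deposited by the authors gives a signal per library and mature miRNA, named normalized counts in its column headers. The normalization formula, the miRNA reference set and a genome build are not given in the sources used here, and no coordinates were assigned. Names are printed as the table gives them, with a species prefix and, on some, a suffix for differences from the reference entry. Predicted candidates carry the prefix PC.

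The table holds 888 entries with 728 distinct mature sequences. Of these, 153 sequences stand on more than 1 entry, always with the same values, and 160 repeats were dropped. Within a library, low values of sequences with a single entry fell on multiples of one step, taken as the value of 1 read: 86.6% to 93.9% did so within 0.1 read. The step ran from 0.898 to 1.19 over the libraries. Sequences with several entries lay on fractions of it, as when reads are divided between entries, so that whole reads could not be recovered for the whole table. The values were therefore not treated as counts. The number of reads behind each library, 5737551 to 8578713, was estimated as the total divided by the step, and 3 reads, used as the floor for values of 0, correspond to 2.69 to 3.56. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The 278 sequences tested hold at least 99.98% of each total.

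All 9 libraries were fitted together with limma 3.58.1 in R 4.3.3 (limma-trend) on log2 of the value plus 1, for sequences at 10 or more in at least 3 libraries, with a mean per group and no further term. There were 4 comparisons: the hybrid against each parent, P. vachelli against P. fulvidraco, and the hybrid against the mean of both parents on the log2 scale. P-values were two-sided and adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. They measure the spread between these samples, since the labels do not say whether a replicate is a fish, an aquarium or a pool. Replicate numbers did not pair the libraries across groups: for 1 of 9 libraries the deviations correlated best with one of the same number. Hybrid classes were set by the 3 pairwise tests and the order of the group means, and failing a test does not show equality. The position of the hybrid is its distance from P. fulvidraco divided by the distance between the parents. Additive hybrids were simulated 100 times with the residual spread of the fit. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

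Lists of miRNA families were tested with camera at an inter-gene correlation of 0.01, with the correlation estimated from the data, and with fry, and adjusted over the lists within a comparison. The 16 lists were liver-enriched, lipid and cholesterol metabolism, let-7 and growth or insulin signalling, miR-17-92 and its paralogous clusters, the early embryo miR-430 group, stress and hypoxia, erythroid, leukocyte and inflammation, endothelial, skeletal and heart muscle, smooth muscle and fibroblast, epithelial, exocrine and endocrine pancreas, neural, sensory (the miR-183 cluster) and Hox-embedded. At least 3 tested sequences were needed, which 14 lists had. Lists, tests, comparisons and the rule for naming miRNAs were chosen before the data were examined. The rule takes, per comparison and direction, the 8 largest fold changes among called miRNAs at or above the median level whose groups do not overlap (with no overlap rule for the mid-parent), at most 3 of them without a known name. It adds the 5 most abundant called miRNAs per direction, up to 4 members per list with the smallest p, the 10 most abundant miRNAs, up to 8 of each class outside the parental range, and the miRNAs detected in one parent. From these the text gives mainly those whose calls were kept with every library left out, a choice made after their values were seen. Calls printed for other comparisons of a miRNA than the one that named it, ccr-let-7j, and the miRNAs singled out for their variation were also chosen after the values were seen.

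Alternatives covered the scaling (median ratios, equal totals, and equal totals without the most abundant miRNA), the pseudocount, the filter, the trend, voom weights, a block for the replicate number, a 2-fold minimum, pairs of groups fitted alone, all entries of the table, sums by family and arm, an arithmetic mid-parent, and each library left out. The method was tested on simulated data, drawn as independent normal values with the spread that limma fitted for each miRNA, equal in all groups. At 2-fold, 71.5% to 84% of the changed miRNAs were recovered over the 4 comparisons, at 1.5-fold 42.8% to 54.5% and at 4-fold 95.8% to 96.8%. None of the calls had the wrong direction (0), and the false share of calls was 3.7% to 4.6%. These shares hold for data that meet the assumptions of the fit. Count models of the whole table were left out, since the values are not counts. Voom weights used values divided by the step, and exact intervals used estimated reads rounded to whole reads. Targets of miRNAs and the transcript and protein data of the study were not analysed here.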

Results

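Small RNAs of juvenile liver were sequenced from 3 lines of catfish, with 3 libraries per line. The lines were P. vachelli, P. fulvidraco and their hybrid Huangyou-1, bred from P. fulvidraco females and P. vachelli males, and each line was kept in 3 aquaria. The study's title concerns heterosis, so the comparisons ask how the liver miRNAs of the hybrid lie between those of its parents. Values are normalized read counts per mature miRNA sequence, given as mean ± SD over the 3 libraries of a line. For the 67 tested sequences with more than 1 entry they are the value of a single entry, which may hold only part of the reads. The estimated number of reads behind a library was 7076487 to 8578713 in P. vachelli, 5737551 to 6469200 in the hybrid and 6336148 to 7425497 in P. fulvidraco. A total of 278 distinct sequences in 124 families reached the minimum of 10 in at least 3 libraries, 262 of them with a known miRNA name. With the entries of a sequence summed, the 10 most abundant sequences of a library held 68.2% to 73.8% of its total. The liver miRNA ssa-miR-122-5p was the most abundant in every library, with 27.9% to 33.1%. It averaged 2511977 ± 252152 in P. vachelli, 1799864 ± 64931 in the hybrid and 2011297 ± 129762 in P. fulvidraco. Ranked by the mean value of a single entry, the other 9 most abundant were ssa-let-7a-5p, cgr-miR-100-5p_R+1, ssa-miR-126-3p, ssa-let-7a-5p_2ss12GA16TA, tni-miR-22a, fru-miR-21, dre-miR-26a-5p, ccr-miR-146a and dre-miR-199-5p. Across miRNAs, which are not independent replicates, Pearson's r of log2 values was 0.984 to 0.997 between libraries of one line. It was 0.967 to 0.974 between P. vachelli and the hybrid, 0.961 to 0.969 between the hybrid and P. fulvidraco, and 0.925 to 0.936 between the parents. On the first principal component, with 66.4% of the variance, the hybrid lay between the parents, and the second, with 14.3%, set it apart from both.

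**Figure D1:**
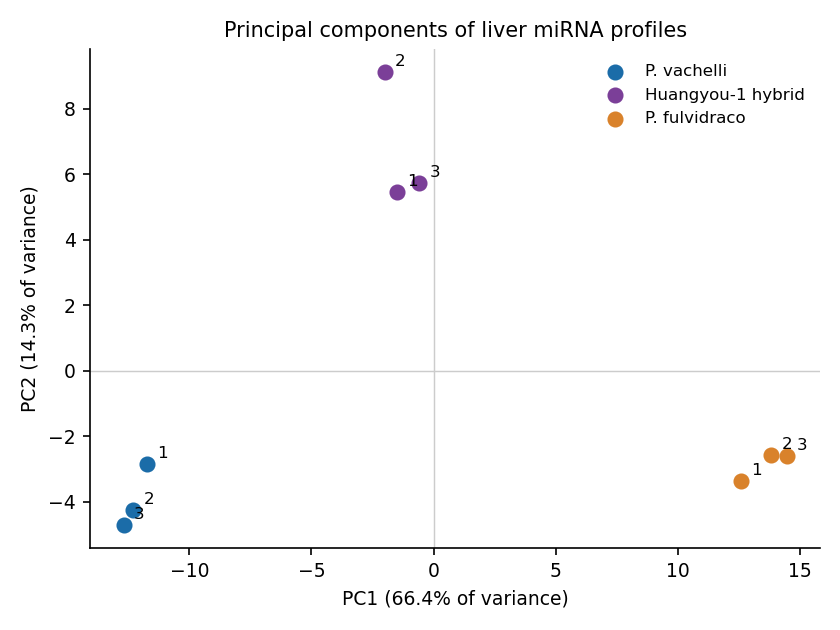
First principal component (horizontal, 66.4% of the variance) and second (vertical, 14.3%) of log2 normalized read counts, where each point is a library and colour marks the line. On the first component the hybrid libraries sit at -2 to -0.6, between P. vachelli at -12.69 to -11.75 and P. fulvidraco at 12.59 to 14.45.

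The comparison of the parental species gives the distance against which the hybrid is read. P. vachelli livers held 82.1 ± 12.1 of dre-miR-31_L+1 against 6 ± 2.34 in P. fulvidraco (log2 fold change 3.62, SE 0.32, adjusted p = 1.72e-05), and also more of the cardiac and slow-muscle miRNA aca-miR-499-5p_R-1 (40.8 ± 8.52 against 2.62 ± 0.95, which is near the floor of 3 reads; log2 fold change 3.54, adjusted p = 1.4e-05). P. fulvidraco livers held more of aca-miR-125a-5p (11043 ± 7778 against 626 ± 96.2; log2 fold change -3.93, SE 0.47, adjusted p = 9.08e-05) and of dre-let-7d-5p (3269 ± 1997 against 376 ± 10.5; log2 fold change -2.96, adjusted p = 0.000245). The erythroid miRNAs ssa-miR-144-5p_R-1 and dre-miR-451, which are processed from neighbouring precursors in vertebrates, were lower in P. vachelli, with log2 fold changes of -1.75 (adjusted p = 0.000278) and -1.13 (adjusted p = 0.000543). The opposite arm of the miR-451 precursor went the other way. Its sequence aca-miR-451-3p_L+2R+1 stood at 384 ± 86.3 in P. vachelli and 47.8 ± 7.92 in P. fulvidraco (log2 fold change 2.97, SE 0.20, adjusted p = 3.5e-06), and dre-mir-451-p3, which lacks its last base, gave a log2 fold change of 2.89 (adjusted p = 7.72e-06). The endothelial miRNAs dre-miR-222a-3p_R-1, bta-miR-221 and ssa-miR-126-3p were higher in P. vachelli, by 1.04 (adjusted p = 4.86e-05), 0.80 (adjusted p = 6.7e-05) and 0.61 (adjusted p = 0.000393) on the log2 scale. So were ssa-miR-92b-3p at 1.33 (adjusted p = 1.26e-05), tni-miR-22a at 1.02 (adjusted p = 7.14e-05) and tni-miR-27e_R-1_1ss19AT at 1.40 (adjusted p = 0.000185). P. fulvidraco had more of aca-miR-9-5p_R+3 (273 ± 84.6 against 59.9 ± 26; log2 fold change -2.20, adjusted p = 0.000805), a family known from neural tissue, and of chi-miR-190a-5p (log2 fold change -1.49, adjusted p = 6.1e-06). Among muscle miRNAs, aca-miR-1a-3p was lower in P. vachelli, at -1.90 (adjusted p = 0.000393), whereas dre-miR-206-3p was higher, at 1.59 (adjusted p = 0.0015). For every miRNA named in this paragraph so far, the 3 libraries of one species lay apart from the 3 of the other, and no call was lost when any single library was left out. The latter was a reason for naming them and is no separate support.

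In all, 143 of 278 miRNAs differed between the parents, 86 higher and 57 lower in P. vachelli, and 75 of them by at least 2-fold (40 higher and 35 lower). Groups of libraries did not overlap for 165 miRNAs (59.4%), where chance gives 10%. Scaling the libraries to equal totals shifted the median log2 fold change of all miRNAs from -0.05 to -0.35 and turned the split to 53 higher and 87 lower. With it ssa-let-7a-5p, ssa-let-7a-5p_2ss12GA16TA, dre-miR-26a-5p and ccr-let-7j changed sign, with log2 fold changes of -0.004, -0.09, -0.01 and -0.07, and ssa-miR-122-5p, at 0.32 (adjusted p = 0.00646) in the deposited scaling, went to 0.02 (adjusted p = 0.769). Of the miRNA lists fixed beforehand, the endothelial one was higher in P. vachelli by camera (9 of 15 miRNAs higher, also 9 adjusted over the list alone; adjusted p = 0.0475). That call was lost with the correlation estimated from the data (adjusted p = 0.279) and with equal totals (adjusted p = 0.0998, and 0.0961 without the most abundant miRNA). Median ratios (adjusted p = 0.0503), the replicate block (0.0696) and sums by family and arm (0.184) ended the call too. It was also lost without P. vachelli library 3 (0.0673), hybrid library 1 (0.0611), 2 (0.0547) or 3 (0.0622), or P. fulvidraco library 2 (0.0752) or 3 (0.0537), where each value is the adjusted p. In the smooth muscle and fibroblast list, 9 of 14 miRNAs were higher, also 9 adjusted over the list alone, but the list test was not passed (adjusted p = 0.0906). The erythroid list was divided, with both 3' arm sequences of miR-451 higher and 5 miRNAs lower (adjusted p = 0.323). Across the 13 lists that were not past the threshold, the adjusted p ran from 0.0906 to 0.896.

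Against its paternal species P. vachelli, the hybrid had far more aca-miR-125a-5p (10489.6 ± 4966 against 626 ± 96.2; log2 fold change 3.95, SE 0.47, adjusted p = 0.000263) and dre-let-7d-5p (2597 ± 1080.3 against 376 ± 10.5; log2 fold change 2.69, SE 0.40, adjusted p = 0.000741), both near their level in P. fulvidraco. The skeletal and heart muscle miRNAs aca-miR-1a-3p and aca-miR-133a_L-1R+1 rose by 1.81 (adjusted p = 0.000835) and 1.60 (adjusted p = 0.00297) on the log2 scale. Of the erythroid miRNAs, ssa-miR-144-5p_R-1 rose by 1.39 (adjusted p = 0.00167), ssa-miR-144-3p_R+1 by 1.17 (adjusted p = 0.000952) and dre-miR-451 by 0.83 (adjusted p = 0.00462), and dre-miR-2188-5p_R+1 rose with them (16369 ± 3871 against 7062 ± 286; log2 fold change 1.19, adjusted p = 0.000443). Of the miRNAs of white blood cells and inflammation, ccr-miR-146a, a feedback regulator of innate immune signalling, rose from 138941 ± 14474 to 246455 ± 28697 (log2 fold change 0.83, SE 0.11, adjusted p = 0.000356), and dre-miR-142a-3p_R-1 rose by 0.74 (adjusted p = 0.00188). Large decreases were seen in dre-miR-31_L+1 (11.5 ± 3.35 against 82.1 ± 12.1; log2 fold change -2.76, SE 0.32, adjusted p = 0.000263) and aca-miR-499-5p_R-1 (log2 fold change -2.11, adjusted p = 0.000585). The miRNAs of the endothelial list, arms and variants of 4 families, were lower as a group. ssa-miR-126-3p, which maintains vessel integrity, stood at 223362 ± 16378 against 354449.6 ± 31935 (log2 fold change -0.66, SE 0.09, adjusted p = 0.000427). bta-miR-221 changed by -0.91 (adjusted p = 0.000154), dre-miR-222a-3p_R-1 by -0.97 (adjusted p = 0.000263), dre-miR-222a-5p by -1.09 (adjusted p = 0.000263) and ssa-miR-126-3p_1ss18AG by -1.01 (adjusted p = 0.000411). Also lower were ssa-miR-92b-3p at -0.98 (adjusted p = 0.000263), and the metabolic regulators dre-miR-27b-3p_R-1 at -0.71 (adjusted p = 0.000443), tni-miR-27e_R-1_1ss19AT at -1.14 (adjusted p = 0.000959) and fru-miR-103 at -0.61 (adjusted p = 0.000356). The abundant liver miRNAs ssa-miR-122-5p, ccr-miR-192_R+1 and tni-miR-22a gave log2 fold changes of -0.48 (adjusted p = 0.000978), -0.76 (adjusted p = 0.000356) and -0.76 (adjusted p = 0.000835). For every miRNA named in this paragraph so far, the hybrid libraries lay apart from those of P. vachelli, and the call was kept with each single library left out. Being kept was a reason for naming them, so it is no separate support. For sha-miR-125a, an abundant sequence of the same family as aca-miR-125a-5p, the hybrid and P. vachelli libraries overlapped.

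Of 278 miRNAs, 97 differed between the hybrid and P. vachelli, 43 higher and 54 lower, and 42 by at least 2-fold (27 higher and 15 lower). Groups did not overlap for 130 miRNAs (46.8%; chance, 10%). Equal totals shifted the median log2 fold change of all miRNAs from -0.01 to 0.34 and turned the split to 87 higher and 26 lower. Under that scaling ssa-miR-122-5p kept a small decrease (log2 fold change -0.13, adjusted p = 0.0339), dre-miR-26a-5p lost its call (adjusted p = 0.0576), and fru-miR-200a_R+1 and xtr-miR-200b changed sign. The endothelial list passed camera (8 of 15 lower, 11 lower adjusted over the list alone; adjusted p = 8.35e-05), also with the estimated correlation (adjusted p = 0.0374) and with equal totals (adjusted p = 2.62e-05). Its 15 sequences come from 4 families, and with sums by family and arm it passed too (adjusted p = 0.00056). The erythroid list passed narrowly (5 of 8 higher, 6 higher adjusted over the list alone; adjusted p = 0.0452). It did not pass with the estimated correlation (adjusted p = 0.46), with equal totals (0.0914, and 0.0888 without the most abundant miRNA), without the trend (0.0518) or with sums by family and arm (0.17). Nor did it pass without P. vachelli library 2 (0.0905, with 3 members higher), hybrid library 1 (0.128) or 3 (0.0665), or P. fulvidraco library 1 (0.053) or 2 (0.0535). In the lipid and cholesterol metabolism list 7 of 18 miRNAs were lower, also 7 adjusted over the list alone, and the list test gave an adjusted p of 0.163. Across the 12 lists that were not past the threshold, the adjusted p ran from 0.163 to 0.871.

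**Figure D2:**
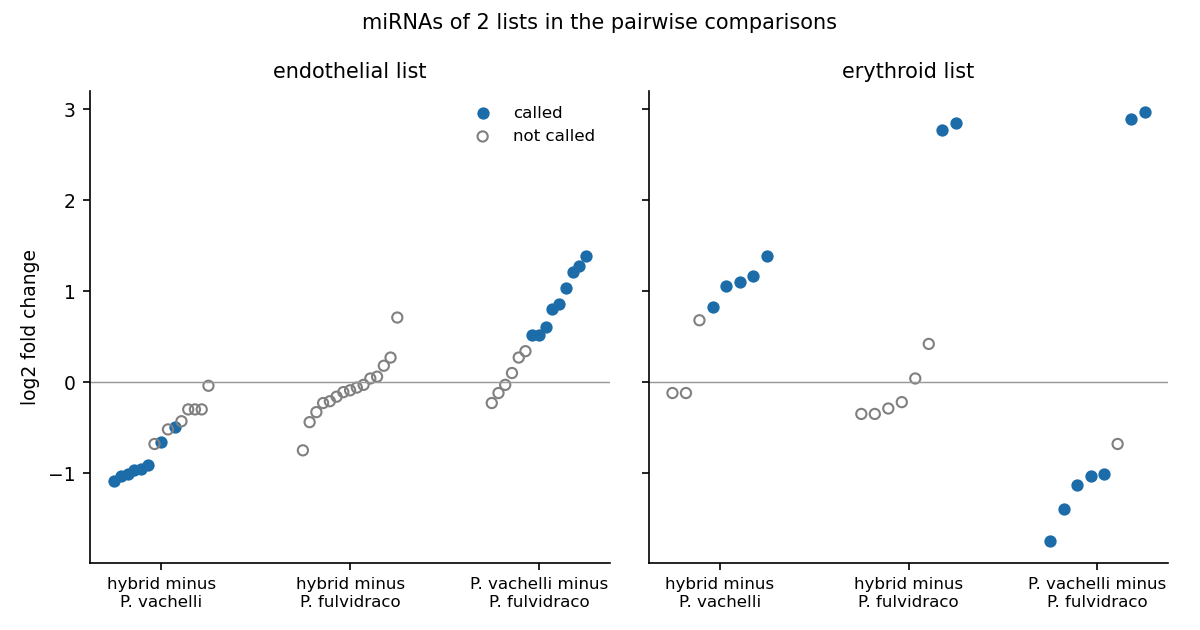
Log2 fold change (vertical axis) of each endothelial and erythroid miRNA in the 3 pairwise comparisons (horizontal axis). Each point is a miRNA and filled points passed limma. In the hybrid against P. vachelli, 8 of the 15 endothelial miRNAs were lower and 5 of the 8 erythroid ones higher.

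Against its maternal species P. fulvidraco, the hybrid differed in fewer miRNAs. It held 351 ± 52.5 of aca-miR-451-3p_L+2R+1, near the level of P. vachelli, where P. fulvidraco held 47.8 ± 7.92 (log2 fold change 2.85, SE 0.20, adjusted p = 7.54e-06), and dre-mir-451-p3 gave 2.77 (adjusted p = 1.73e-05). The p53-responsive dre-miR-34a was higher in the hybrid (486 ± 60.8 against 219 ± 24.4; log2 fold change 1.15, SE 0.18, adjusted p = 0.00277), as was aca-miR-499-5p_R-1, at 1.44 (adjusted p = 0.00953). The mesenchymal miRNAs ssa-miR-199a-5p_1ss11AG and ssa-miR-143-5p were higher by 1.03 (adjusted p = 0.00286) and 0.70 (adjusted p = 0.00899). Smaller increases were seen in the abundant cgr-miR-100-5p_R+1 (318704 ± 10568 against 214111 ± 16229; log2 fold change 0.58, SE 0.09, adjusted p = 0.00277) and fru-miR-21 (log2 fold change 0.50, adjusted p = 0.00899). The lymphocyte-associated pma-miR-181a-5p and gga-miR-181b-5p_R+1 were higher at 0.60 (adjusted p = 0.00416) and 0.72 (adjusted p = 0.00277), and ccr-miR-146a at 0.67 (adjusted p = 0.00277). Lower in the hybrid were aca-miR-9-5p_R+3 (77.2 ± 22 against 273 ± 84.6; log2 fold change -1.80, SE 0.36, adjusted p = 0.00855), aca-miR-9-1-3p_R+2 (log2 fold change -2.04, adjusted p = 0.0046) and chi-miR-190a-5p (563 ± 18.7 against 874 ± 25.9; log2 fold change -0.63, adjusted p = 0.00417). For every miRNA named in this paragraph so far, the hybrid libraries lay apart from those of P. fulvidraco and the call was kept with each single library left out. They were chosen for being kept, which is therefore no separate support. For hsa-miR-29b-2-5p_R+1_1ss18CT, also lower (log2 fold change -0.94, adjusted p = 0.00961), the call but not the direction was lost without P. fulvidraco library 3 (adjusted p = 0.0535). Other calls were lost without that library too, among them ssa-let-7f-5p_1ss19TA, lower (adjusted p = 0.0604), and ccr-miR-15b, higher (adjusted p = 0.132).

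Of 278 miRNAs, 54 differed between the hybrid and P. fulvidraco, 36 higher and 18 lower, and 25 by at least 2-fold (19 higher and 6 lower). The count was 30 without P. fulvidraco library 3. Groups did not overlap for 101 miRNAs (36.3%; chance, 10%). Equal totals shifted the median log2 fold change of all miRNAs from 0.06 to 0.11 and gave 37 miRNAs higher and 16 lower. Of the 53 calls whose miRNAs were tested under both scalings, 49 were kept. By camera 0 of the 14 lists passed, against 1 at an unadjusted p under 0.05 and 5 by fry, with adjusted p from 0.318 to 0.812. Without hybrid library 2 the let-7 and growth list passed (adjusted p = 0.0459). The endothelial miRNAs, lower in the hybrid than in P. vachelli, did not pass against P. fulvidraco as a list (adjusted p = 0.477). By limma 0 of its 15 miRNAs differed, also 0 adjusted over the list alone, against 3 at an unadjusted p under 0.05 (1 higher and 2 lower). The erythroid list had both 3' arm sequences of miR-451 higher, also 2 adjusted over the list alone, with a median log2 fold change of -0.09 and a mean of 0.61 (adjusted p = 0.567).

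**Figure D3:**
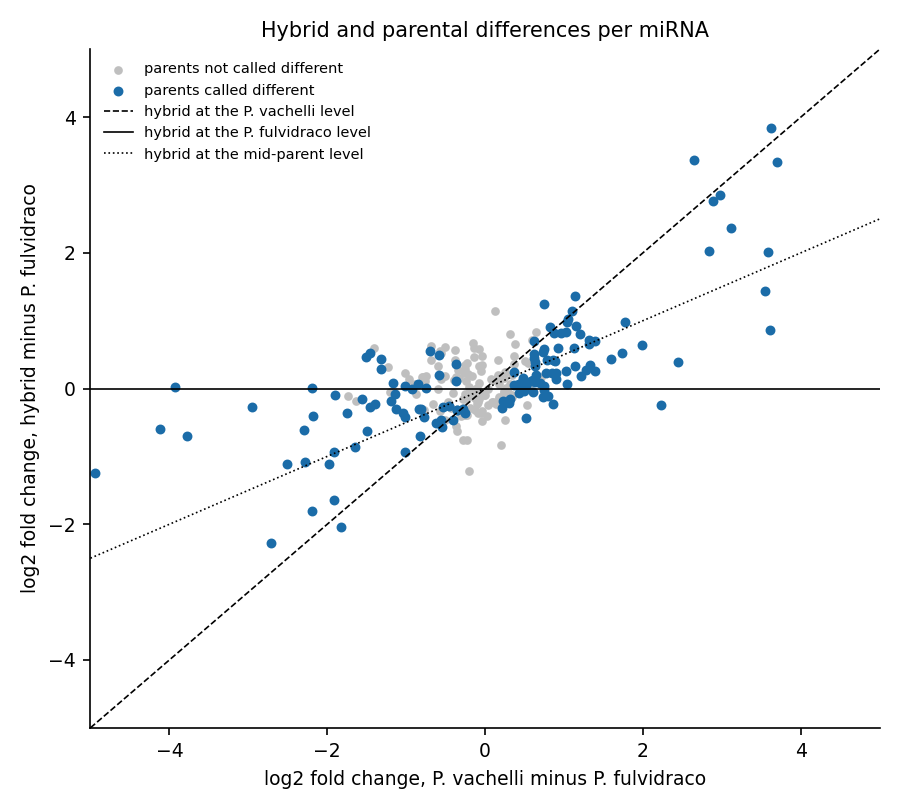
Log2 fold change of P. vachelli against P. fulvidraco (horizontal axis) and of the hybrid against P. fulvidraco (vertical axis). Each point is 1 of 272 miRNAs, and 6 further miRNAs lie outside the axes. Colour marks whether the parents were called different, and hybrid classes are not marked. Lines mark a hybrid at the level of P. vachelli (dashed), of P. fulvidraco (solid) and of the mid-parent (dotted).

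The hybrid was then set against the mid-parent, the mean of both parents on the log2 scale, which a hybrid additive on that scale would match. A clear departure was that of ccr-miR-146a, which stood at 246455 ± 28697 in the hybrid, 138941 ± 14474 in P. vachelli and 154094 ± 8393 in P. fulvidraco (log2 fold change 0.75, SE 0.09, adjusted p = 0.000772). Its other arm, ssa-miR-146a-3p_R-1_2ss9GA20CT, also lay above the mid-parent (log2 fold change 0.90, adjusted p = 0.00326). The miR-451 3' arm aca-miR-451-3p_L+2R+1 was above the mid-parent by 1.37 (adjusted p = 0.000923), with the hybrid near the level of P. vachelli. Below the mid-parent were the endothelial dre-miR-222a-5p (1250.2 ± 55.5; log2 fold change -0.66, SE 0.11, adjusted p = 0.00361) and bta-miR-221 (5582 ± 223; log2 fold change -0.51, SE 0.08, adjusted p = 0.00308), with ola-miR-210-5p_R+2_1ss20TC (log2 fold change -0.59, SE 0.10, adjusted p = 0.00362), from a family induced by hypoxia whose 3' arm sequences ola-miR-210-3p_L-1R+5 and cgr-miR-210-3p_R-2 were not called (adjusted p = 0.202 and 0.386). Of the most abundant miRNAs, ssa-let-7a-5p lay below it, at a log2 fold change of -0.36 (adjusted p = 0.00361), as did dre-miR-26a-5p at -0.35 (adjusted p = 0.00367) and ssa-miR-122-5p at -0.32 (adjusted p = 0.0113), the last of which lost its call without hybrid library 2 (adjusted p = 0.0544), without the trend (0.0622) and without the filter on low values (0.0814). For each miRNA called in this paragraph so far, 3 of 3 hybrid libraries lay on the same side of the mid-parent. In all, 52 miRNAs departed from it, 28 above and 24 below, and 18 by at least 2-fold (17 above and 1 below). The count was 16 without hybrid library 2, 29 without P. vachelli library 2, 28 without P. fulvidraco library 2 and 32 without P. fulvidraco library 3. With equal totals the median log2 difference of all miRNAs moved from 0.06 to 0.24 and the split was 56 above and 8 below. Simulated hybrids that were additive on the log2 scale gave 0.11 such miRNAs on average (range, 0 to 2), and ones additive on the linear scale gave 8.73 (3 to 16). Where the parents differ, the log2 mid-parent lies below the arithmetic one, so a hybrid additive on the linear scale lies above the log2 mid-parent. With an arithmetic mid-parent 35 miRNAs departed, 31 of them among the 52. The endothelial list lay below the mid-parent (5 of 15 lower, 8 adjusted over the list alone, and 2 lower without hybrid library 2; adjusted p = 4.12e-05, and 0.0317 with the estimated correlation). Both miRNAs of the erythroid list called above the mid-parent were sequences of the 3' arm of miR-451, aca-miR-451-3p_L+2R+1 and dre-mir-451-p3, and the other 6 were not called (adjusted p = 0.0649 to 0.653). With an arithmetic mid-parent dre-mir-451-p3 also lost its call (log2 fold change 0.70, adjusted p = 0.0596). The erythroid list as a whole lay above (2 of 8 higher, 4 adjusted over the list alone, adjusted p = 0.0089). It did not with the estimated correlation (adjusted p = 0.396), with sums by family and arm (0.0874) or without hybrid library 1 (0.108). The lipid and cholesterol metabolism list (adjusted p = 0.0572) passed, below the mid-parent, with equal totals (0.0335) and without P. vachelli library 1 (0.0454) or P. fulvidraco library 2 (0.0446) or 3 (0.0317). The liver-enriched list (adjusted p = 0.0846) passed without P. fulvidraco library 2 (0.0446) and stood at 0.05 without P. vachelli library 1.

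Among the expression classes, 68 miRNAs were P. fulvidraco-like, 28 P. vachelli-like, 13 additive, 4 above both parents and 3 below both, while 116 showed no difference and 46 fell in no class. Simulated hybrids additive on the log2 scale gave 25.49 P. fulvidraco-like (15 to 47), 25.44 P. vachelli-like (13 to 42) and 43.22 additive miRNAs (32 to 54). The muscle and heart miRNAs aca-miR-1a-3p and aca-miR-133a_L-1R+1, the endothelial ssa-miR-126-3p and dre-miR-222a-3p_R-1, and aca-miR-125a-5p and dre-let-7d-5p were P. fulvidraco-like. The miR-451 3' arm, dre-miR-34a, aca-miR-9-5p_R+3, cgr-miR-100-5p_R+1 and fru-miR-21 were P. vachelli-like, and chi-miR-190a-5p was additive, at 310.1 ± 5.07, 563 ± 18.7 and 874 ± 25.9 in P. vachelli, the hybrid and P. fulvidraco. Of the 4 above both parents, ccr-miR-146a kept its class with every single library left out. dre-miR-193b-3p (107 ± 15.1, 235 ± 130.2 and 97.1 ± 11.9 in P. vachelli, the hybrid and P. fulvidraco) lost it without any 1 of the 6 parental libraries, with the larger adjusted p at 0.0573 to 0.0929. dre-miR-204-5p (174 ± 32.4, 285 ± 36.6 and 27.3 ± 8.08) exceeded P. fulvidraco with each library left out, by 3.37 (adjusted p = 7.54e-06), but its difference from P. vachelli (log2 fold change 0.72, adjusted p = 0.0456) was lost without any P. vachelli library, hybrid library 1 or 2, or P. fulvidraco library 3 (0.0527 to 0.162). ssa-miR-146a-3p_R-1_2ss9GA20CT lost its class without P. vachelli library 2, hybrid library 2 or 3, or any P. fulvidraco library (0.0637 to 0.146). Of the 3 below both, ola-miR-210-5p_R+2_1ss20TC (5482 ± 217, 3344 ± 247 and 4604 ± 452) lost its class without hybrid library 2 or 3 or P. fulvidraco library 3 (0.0566 to 0.0838). ssa-let-7a-5p_2ss12GA16TA lost it without hybrid library 1 or 3 or P. fulvidraco library 2 or 3 (0.0638 to 0.107), and tni-let-7i without P. vachelli library 2, hybrid library 3 or P. fulvidraco library 3 (0.053 to 0.0707). Over 20 alternative settings, left-out libraries included, ccr-miR-146a kept its class in 19, dre-miR-193b-3p in 13, dre-miR-204-5p and ssa-miR-146a-3p_R-1_2ss9GA20CT in 9 each, ola-miR-210-5p_R+2_1ss20TC in 16, ssa-let-7a-5p_2ss12GA16TA in 11 and tni-let-7i in 13. Median-ratio scaling ended the class of dre-miR-204-5p and ssa-miR-146a-3p_R-1_2ss9GA20CT, and equal totals that of ssa-let-7a-5p_2ss12GA16TA and tni-let-7i. The replicate block ended all 4 of these, analysis without the filter ended dre-miR-193b-3p, dre-miR-204-5p, ssa-miR-146a-3p_R-1_2ss9GA20CT and ssa-let-7a-5p_2ss12GA16TA, and analysis without the trend ended dre-miR-204-5p and ssa-let-7a-5p_2ss12GA16TA. Equal totals without the most abundant miRNA ended ssa-miR-146a-3p_R-1_2ss9GA20CT and tni-let-7i. The count above both was 1 without P. vachelli library 2 or P. fulvidraco library 3, 2 without P. vachelli library 1 or 3, hybrid library 2 or P. fulvidraco library 1 or 2, and 9 without hybrid library 3. That below both was 6 without P. vachelli library 3, 1 without hybrid library 3 and 0 without P. fulvidraco library 3. The overlap of calls against both parents, 4 higher and 3 lower, compares with 5.57 and 3.50 if the tests were independent and with 0 and 0.01 in simulations without any effect.

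**Figure D4:**
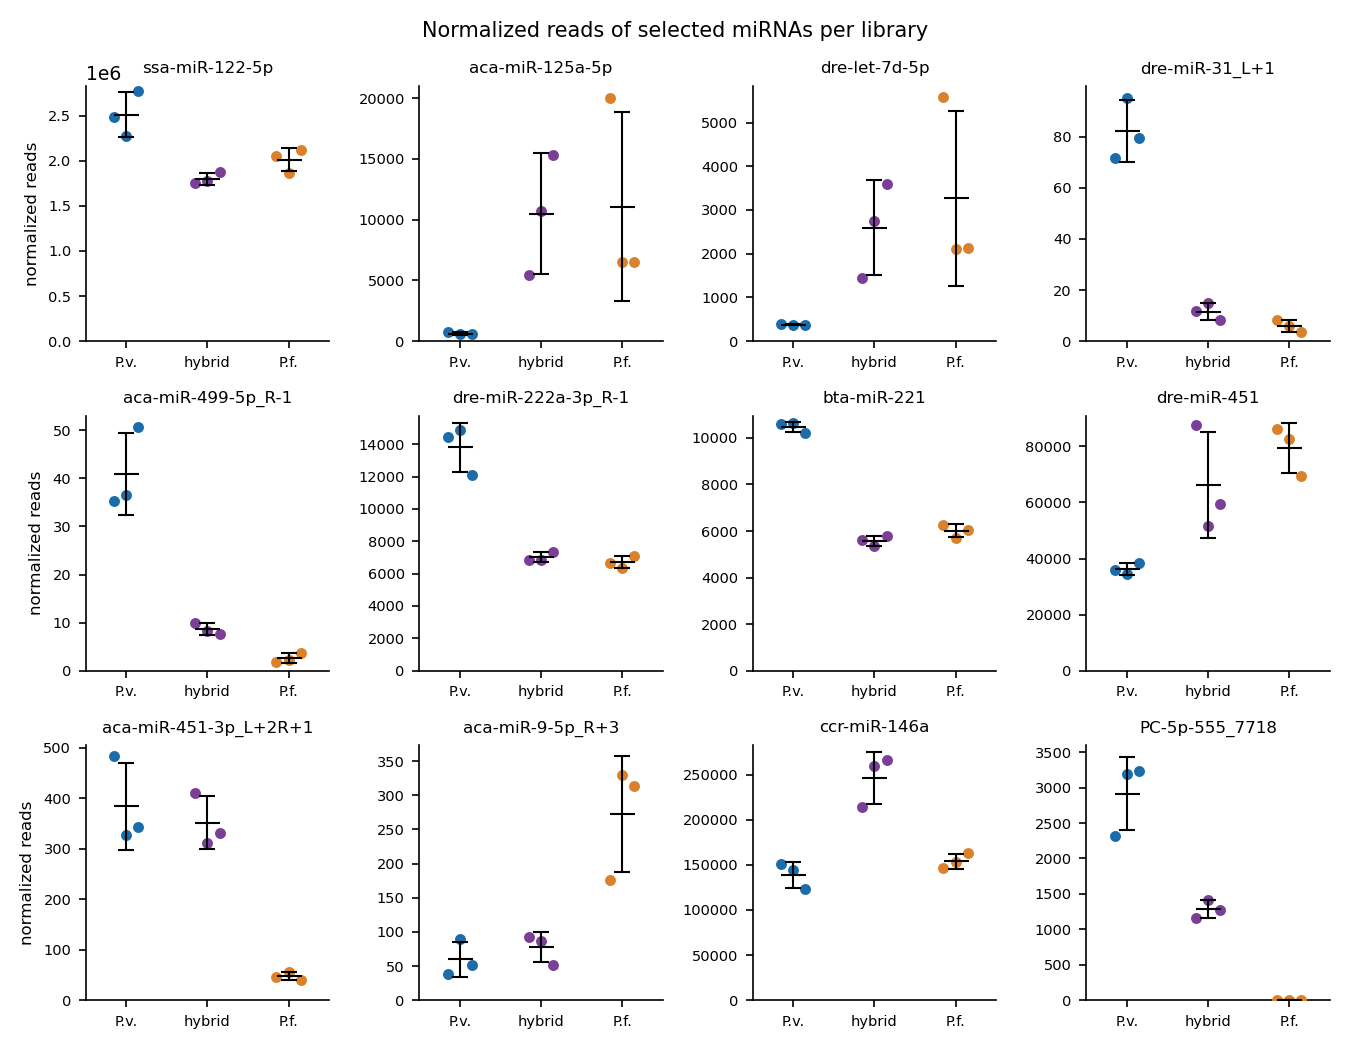
Normalized read count (vertical axes, linear scale) of 12 miRNAs in P. vachelli, the hybrid and P. fulvidraco. Points are libraries and bars mark the mean ± SD. In aca-miR-125a-5p the hybrid lies near P. fulvidraco (10489.6 against 11043), in aca-miR-451-3p_L+2R+1 near P. vachelli (351 against 384), and in ccr-miR-146a above both (246455).

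For the 143 miRNAs that differed between the parents, the position of the hybrid was measured from 0 at P. fulvidraco to 1 at P. vachelli on the log2 scale. The median position was 0.308, and 86 miRNAs (60.1%) lay nearer P. fulvidraco. Taken library by library, the median was 0.324, 0.364 and 0.35 in the 3 hybrid libraries (SD 0.02). The 86 miRNAs higher in P. vachelli had a median of 0.318 and the 57 higher in P. fulvidraco one of 0.262. Among those at least 2-fold apart, the 40 higher in P. vachelli had a median of 0.556. Of these, dre-miR-31_L+1 and aca-miR-499-5p_R-1 lay nearer P. fulvidraco. The 35 higher in P. fulvidraco, such as aca-miR-125a-5p and ssa-miR-144-5p_R-1, had a median of 0.186. Measured on the linear scale, the medians of these sets were 0.416 and 0.325, with 26 of the 40 and 22 of the 35 nearer P. fulvidraco. The side of the midpoint for the 40 thus depends on the scale. Among those less than 2-fold apart, such as ssa-miR-126-3p and bta-miR-221, the medians on the log2 scale were 0.195 and 0.524. Equal totals left the overall median at 0.316, with 0.683 for the 53 miRNAs then higher in P. vachelli and 0.164 for the 87 higher in P. fulvidraco, and leaving out single libraries gave 0.273 to 0.367.

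miRNAs detected in only one parental species were sought as sequences at 0 in 3 libraries of one parent and at 10 or more in each library of the other. In P. vachelli there were 4, all predicted candidates without a known name: PC-5p-3257_591 (268 ± 29.8), PC-5p-17897_142 (70.2 ± 15.7), PC-3p-23565_106 (38.0 ± 12.6) and PC-5p-5068_398 (34.4 ± 12.4). Against a floor of 3 reads per library they were at least 94.4-fold, 24.7-fold, 13.4-fold and 12.1-fold higher than in P. fulvidraco. The hybrid held 29%, 47.6%, 44.1% and 119% of the P. vachelli level, the last with values of 58.5, 62.1 and 2.31 in its 3 libraries. In P. fulvidraco there was 1, PC-5p-30865_77 (29.9 ± 2.95), at least 9.5-fold higher than in P. vachelli, with 40.7% of that level in the hybrid. A further candidate, PC-5p-555_7718, was nearly confined to P. vachelli and the hybrid, at 2916 ± 513 and 1288 ± 127. Only 5 reads fell in P. fulvidraco, a ratio of 1854 between the parents (95% exact Clopper-Pearson interval, 794 to 5713). The hybrid held 44.2% of the P. vachelli level. Such differences in detection can reflect sequence differences between the species or the reference used for mapping as well as expression, and intervals and floors cover counting error only.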

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

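The voom weights, the arithmetic mid-parent and the position on the linear scale were alternatives chosen after seeing the data, and the others were planned. Of 178 called values of named miRNAs, 57 kept their direction and call in all settings run for them, the 2-fold minimum included. The call was lost with the direction kept for 3 under median-ratio scaling, 31 under equal totals, 24 without the trend, 32 without the filter, 31 with the replicate block, 4 with voom weights and 8 to 40 with single libraries left out. Pseudocounts of 0.5 and 10 lost 2 and 3, and the 2-fold minimum lost 111. Equal totals without the most abundant miRNA lost 26 of 175, pairs of groups fitted alone 10 of 146, and the arithmetic mid-parent 8 of 32.

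With equal totals, log2 fold changes reversed to 0.036 for fru-miR-200a_R+1 and 0.009 for xtr-miR-200b in the hybrid against P. vachelli, and to -0.004 for ssa-let-7a-5p and -0.087 for ssa-let-7a-5p_2ss12GA16TA in P. vachelli against P. fulvidraco. The last also reversed, to -0.079, when the most abundant miRNA was left out of the totals. In the same comparison dre-miR-26a-5p and ccr-let-7j, which changed sign with equal totals, then gave -0.003 and -0.066. These scalings move all log2 fold changes of a comparison alike, so small ones change sign. Equal totals put 8 miRNAs above both parents. With an arithmetic mid-parent PC-5p-555_7718 reversed to -0.17, since a log2 mid-parent of a value near 0 lies far below the arithmetic one.

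A minimum of 2-fold left 42, 25, 75 and 18 miRNAs in the hybrid against P. vachelli, the hybrid against P. fulvidraco, P. vachelli against P. fulvidraco and the hybrid against the mid-parent, which follows from its construction. It left 8 additive, 15 P. vachelli-like, 28 P. fulvidraco-like, 1 above and 0 below both parents, and the position became 0.406. The position was 0.348 with equal totals without the most abundant miRNA. Departures from the mid-parent numbered 81 with all entries of the table, 21 without the filter and 30 with the replicate block. The number above both parents was 2 with median ratios, 1 without the filter and 2 with the block, and that below both was 5 with median ratios. With all entries, a sequence with several entries is counted more than once, and all 52 main calls were among the 81. For the other changes the cause was not tested. A minimum of 3 per library gave 12 miRNAs detected in P. vachelli only and 4 in P. fulvidraco only, and a minimum of 30 gave 0 in P. fulvidraco only.

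Lists past the threshold numbered 2, 0, 1 and 2 in the same order of comparisons. In the hybrid against P. vachelli the number was 1 with equal totals, with or without the most abundant miRNA, with the estimated correlation, without the trend and with families summed, and 4 without the filter. In P. vachelli against P. fulvidraco it was 0 with both equal-total scalings, median ratios, the estimated correlation, the block and families summed, and 2 without the filter. Against the mid-parent it was 1 with the estimated correlation and with families summed. Fry, which asks only whether a list moves one way on balance, called 7, 5, 8 and 5 lists. The cause of the changes by camera was not tested.

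Leaving out single libraries gave 74 to 103 changed miRNAs in the hybrid against P. vachelli, 30 to 61 against P. fulvidraco, 111 to 143 in P. vachelli against P. fulvidraco and 16 to 58 against the mid-parent. The lowest came without P. vachelli library 2, P. fulvidraco library 3, P. vachelli library 2 and hybrid library 2. The number departing from the mid-parent was 29 without P. vachelli library 2, 28 without P. fulvidraco library 2 and 32 without P. fulvidraco library 3. Classes ran from 10 to 15 additive, 19 to 33 P. vachelli-like, 52 to 66 P. fulvidraco-like, 1 to 9 above and 0 to 6 below both parents, and the position from 0.273 to 0.367. Lists past the threshold ran from 1 to 2, 0 to 1, 0 to 1 and 1 to 4. In the hybrid against P. vachelli the number was 1 without P. vachelli library 2, hybrid library 1 or 3, or P. fulvidraco library 1 or 2, and in the hybrid against P. fulvidraco it was 1 without hybrid library 2. In P. vachelli against P. fulvidraco it was 0 without P. vachelli library 3, any hybrid library, or P. fulvidraco library 2 or 3, and against the mid-parent it was 1 without hybrid library 1 and 4 without P. fulvidraco library 2. Count models of the whole table were not run, because the values are not counts. Voom weights and the exact intervals used estimated reads. Libraries had 5737551 to 8578713 reads, so a value of 0 allows up to 2.69 to 3.56 (3 reads), and thinner depths were not simulated.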

Other observations

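The splits of the libraries, and the tests of the authors' scaling, of averaging on the linear scale, of blood content for the 3' arm of miR-451, of the pair aca-miR-125a-5p and dre-let-7d-5p and of read exchange with sha-miR-125a, were tests chosen only after the result was seen. Among the lists not described so far, camera gave adjusted p in the hybrid against P. vachelli of 0.188 for the liver-enriched miRNAs, 0.752 for let-7 and growth, 0.203 for miR-17-92 and its paralogs, 0.871 for stress and hypoxia, 0.267 for leukocyte and inflammation and 0.561 for skeletal and heart muscle. It gave 0.203 for smooth muscle and fibroblast, 0.213 for epithelial, 0.203 for pancreas, 0.265 for neural and 0.578 for Hox-embedded miRNAs. Members of some of these lists went opposite ways: in leukocyte and inflammation 5 of 15 were higher, among them ccr-miR-146a and dre-miR-142a-3p_R-1, and 3 lower, among them gga-miR-181b-5p_R+1, also 5 and 3 adjusted over the list alone. In the muscle list 3 of 6 were higher, among them aca-miR-1a-3p and aca-miR-133a_L-1R+1, and 2 lower, among them aca-miR-499-5p_R-1, also 3 and 2 adjusted over the list alone. The median, mean and test of a list differed in sign in 10 of 56 list results, 0 of which passed. The early embryo list had 0 tested miRNAs. The sensory list had 1, gga-miR-183_R-1, at 15.4 ± 1.45 in P. vachelli and 3.24 ± 4.02 in the hybrid (log2 fold change -2.47, adjusted p = 0.016; lost without P. vachelli library 2, adjusted p = 0.056). In 20 simulations in which no list was moved, 2 gave a list past the threshold.

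Some miRNAs varied widely between libraries of one line. The pancreatic islet miRNA tni-miR-375 had the largest within-line SD among miRNAs at or above the median level, 0.95 on the log2 scale. It ran from 424 to 993 in P. vachelli, 1111 to 4442 in the hybrid and 633 to 2298 in P. fulvidraco. The exocrine pancreas miRNA ccr-miR-217 (within-line SD 0.54) ran from 3137 to 7271 in P. vachelli, 4947 to 8509 in the hybrid and 3807 to 8020 in P. fulvidraco. The fragment hsa-mir-7641-2-p3 (SD 0.56) ran from 1318 to 4239 in the hybrid, and aca-miR-19a-3p_R+1 (SD 0.56) from 777 to 2257 in P. vachelli, each the line with its widest range.

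For each pairwise comparison, the 6 libraries allow 10 splits, too few for a share under 0.05: the real split gave 97, 54 and 143 miRNAs, the highest other gave 0, and 1 split, the real one, reached the real count in each. Of 100 splits of the 9 libraries, 4 gave as many departures from the mid-parent as the real 52, the real one included, and the highest other gave 101. The splits that gave more, or nearly as many, put 3 P. vachelli libraries (94 to 101) or 3 P. fulvidraco libraries (46) in the place of the hybrid, which points to the structure of the samples, in which each line stands apart. For miRNAs above or below both other groups, 5 of 100 splits, the real one included, gave at least the real 7, the highest other giving 69, a share of splits that does not exclude chance. The other 4 splits are again those with 3 libraries of one parent in the place of the hybrid, a structure of the samples, and every split that mixed the lines gave 0. Mixed splits carry the differences between lines in their spread, so both shares mainly follow how often an intact line was drawn, and chance is not read as excluded for either count. Simulated hybrids additive on the log2 scale gave 0.07 above both parents (0 to 1) and 0.12 below both (0 to 2) on average.

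The hybrid lay nearer P. fulvidraco in the miRNAs that differ between the parents, at a median position of 0.308, but other measures pointed to P. vachelli: the median correlation of libraries was 0.97 with P. vachelli and 0.964 with P. fulvidraco, and the hybrid lay nearer P. vachelli on the first principal component. The 95 miRNAs outside the 8 lists of other cell types gave 0.365 (SD over hybrid libraries 0.023), under the midpoint. The position was thus not confined to the listed families. RNA of other cell types stays open as a cause, since miRNAs outside the lists can come from other cells too. Averaging of parental values on the linear scale is argued against in the deposited scaling, since the median linear position was 0.308 (SD 0.053). These SDs leave out the spread of the parental libraries. The authors' scaling of the libraries stays open: a slope with an intercept, which no factor per library moves, gave 0.428 by the median of pairwise slopes (SD 0.032) and 0.574 by least squares (SD 0.049), on opposite sides of the midpoint. A maternal or dominance effect on liver miRNAs may contribute but was not tested, and reciprocal crosses would test it.

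The 3' arm of miR-451 was far lower in P. fulvidraco than in P. vachelli. With its sequences summed, the hybrid stood near P. vachelli (770 against 830). As a share of dre-miR-451, however, the arm in the hybrid lay between the parents. Blood content of the liver is argued against for this arm, since the arm amounted to 2.29% of dre-miR-451 in P. vachelli, 1.18% in the hybrid and 0.135% in P. fulvidraco. The log2 ratio of the arm to dre-miR-451 differed between the species by 4.07 (SE 0.121; exact permutation p = 0.1, two-sided, the smallest that 20 permutations allow). Reads of the 3' arm listed under other names are argued against, since 0 other sequences of the table matched its first 17 bases within 4 mismatches. A variant of the P. fulvidraco precursor may change its processing or keep its reads from matching the reference, which small RNA reads aligned to a P. fulvidraco genome would test. For ssa-miR-144-5p_R-1 and dre-miR-451 themselves, lower in P. vachelli, blood content cannot be told apart from regulation: 5 of 6 miRNAs were called, all lower, but their deviations within lines correlated only moderately (median 0.401).

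aca-miR-125a-5p and dre-let-7d-5p varied together between libraries of one line. Deviations from the line means over the 9 libraries gave Pearson's r = 0.989 and Spearman's rho = 0.983, each with an exact within-line permutation p of 0.00463, the smallest that 216 permutations allow, and r = 0.965 without the 2 farthest libraries, P. fulvidraco library 1 and hybrid library 3. The pair was chosen after its values were seen, and 3 of 38503 pairs of tested miRNAs were as high. A factor shared by all miRNAs of a library is argued against, since the other 276 miRNAs followed aca-miR-125a-5p with a median r of 0.039. An exchange in which the abundant sha-miR-125a loses the reads that aca-miR-125a-5p gains is argued against. Its deviations rose with those of aca-miR-125a-5p (r = 0.78, exact permutation p = 0.00463, and rho = 0.8, exact permutation p = 0.0139). Without the same libraries r was 0.665. The test cannot tell whether some reads of sha-miR-125a were counted under aca-miR-125a-5p, which would also give a positive correlation. No biological explanation of the pattern was tested.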
